A study of Homo sapiens with 12 samples.

How the data were processed

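CUT&RUN for H3K27me3 was analysed in 8 libraries of MDA-MB-231 cells: EV (n = 3), OE1 (n = 2) and OE4 (n = 3). The series text describes the libraries as biological triplicates, or duplicates in part, and whether they came from separate cultures is not stated. The 4 other samples of the list are IgG libraries, which were not used here, and the NOP16 knockout arm that the series text mentions was not analysed here. Reads were aligned with Bowtie2 and broad peaks called with MACS2 on hg38, per the submitters' processing notes, which give no versions, thresholds or control library. No peak ended past its hg38 chromosome length (0 in every library).

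The deposited peak lists give each peak's coordinates and 4 values. The score in the deposited lists is 10 times the peak's -log10 q without its decimals. The fold enrichment is a linear ratio over the caller's own background, as the authors' caller wrote it. The -log10 p and -log10 q of each peak are deposited as averages over the peak, and the smallest -log10 q was between 1.30 and 1.32 in every library. The peaks were called by the authors in each library separately and were not normalized to each other. The lists hold no counts, so the depth is unknown, no interval that needs counts could be given, and a value of 0 means that no peak was listed.

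Peaks on chromosomes 1 to 22 and X were used as listed, without merging. TSS windows spanned 5 kb either side of the annotated start of each protein-coding gene of GENCODE 44 on these chromosomes. The percentage covered by peaks was computed per library for TSS windows and for 50 kb bins. This covered percentage was the replicated value. Features with a mean covered fraction of at least 0.05 over all libraries were tested with limma 3.58.1 in R 4.3.3 (trend and robust empirical Bayes), with Benjamini-Hochberg adjustment and a threshold of 0.05. Both OE lines were compared with EV as 2 groups, so a result for both lines comes from the pooled libraries and need not pass in each line. OE1, OE4 and the difference between them were tested in a model of 3 groups with a common spread. Covered length, peak number, peak width, domains and chromosome shares were compared by two-sided exact permutation tests. Overlap between libraries was the Jaccard index of covered bases for all 28 pairs. The correlation of the lines' changes was set against 100 simulations of unchanged groups that share the EV libraries. Gene lists with at least 5 tested members were tested with camera (preset correlation 0.01, and an estimated correlation beside it). Coverage, overlaps, permutations and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

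The tests, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except where stated. The 20 lists were HOX genes, developmental transcription factors, ribosomal protein genes, ribosome biogenesis and nucleolar genes, PRC2 and H3K27 demethylase genes, luminal epithelial genes, basal epithelial genes, mesenchymal genes, cell cycle inhibitors and tumour suppressors, proliferation genes, interferon and antigen presentation genes, cytokine and chemokine genes, clustered protocadherins, olfactory receptors, ZNF zinc finger genes, replication-dependent histone genes, imprinted genes, neuronal channel and receptor genes, haematopoietic markers, and hepatocyte and muscle markers. The named genes were NOP16, and for each contrast with EV the 10 largest gains and 10 largest losses past the threshold with all OE libraries beyond all EV libraries. Each list added up to 4 tested members with the largest difference and up to 4 with the highest EV cover. Named regions were the 5 bins with the largest gain and the 5 with the largest loss, adjacent bins joined. Genes named outside this rule are said to be so, except in the runs of bins and among windows with peaks in all EV or all OE libraries alone. Genes there, HIGD2A included, were named from the results.

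Alternatives were peaks with -log10 q of at least 3, the peaks above the library median in fold, equal covered length (the peaks of highest -log10 p up to the length of the library that covers least), merging peaks closer than 3000 bp, windows of 2 kb, gene bodies with 2 kb upstream, no filter or a mean of at least 0.2, arcsine square root, quantile normalization, limma without trend and robust, a 3-group design for both lines, the replicate number as a block, 10 kb bins, at least 50% of the window for a window to count as covered, and leaving out each library. Normalization within GC deciles and quantile normalization for the gene lists, and a division of the EV libraries between the OE1 and OE4 contrasts, were added after the data were seen. For peaks within NOP16 an implied background was derived from each peak's fold and -log10 p under a Poisson model, and divided by its median over the library's peaks.

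The code was tested on simulated data. Covered percentages were right in all of 300 random interval sets. In simulated TSS windows for both lines, differences of 10, 20 and 40 points were recovered in 1.27%, 22.2% and 98.3% of cases, with 4 false calls among 76. The same sizes were recovered in 0, 12% and 83.6% for OE1 (2 false of 62 calls), in 3.33%, 19.2% and 90.3% for OE4 (1 of 74), and in 18.6%, 81.2% and 100% of 50 kb bins for both lines (6 of 137).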

Results

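H3K27me3, the repressive histone mark laid down by Polycomb repressive complex 2, was mapped by CUT&RUN in MDA-MB-231 cells, an established line from a triple-negative breast cancer. In CUT&RUN an antibody directs a nuclease to the mark in intact nuclei, and the released fragments are sequenced. The 8 libraries came from 3 stable lines: an empty vector control (EV, n = 3) and 2 lines overexpressing the nucleolar protein NOP16, OE1 (n = 2) and OE4 (n = 3). Each library was represented by its own list of broad peaks on hg38. The peaks on the autosomes and chromosome X numbered 78295, 88631 and 75921 in EV, and 79980 and 71461 in OE1. In OE4 they numbered 76066, 84965 and 78083. Peak lists hold no read counts, so the depth of each library is unknown, and each value below is a length or percentage covered by peaks.

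The first question was whether NOP16 overexpression went with a different extent of H3K27me3 across the genome, as the series title asks. Peaks covered 150 ± 26.4 Mb in EV (SD, n = 3) and 122 ± 18.0 Mb in the OE libraries (SD, n = 5), which was 4.95% and 4.04% of the chromosomes. OE1 covered 114 ± 15.7 Mb (SD, n = 2) and OE4 128 ± 19.8 Mb (SD, n = 3). The EV and OE ranges overlapped, and the difference did not pass a two-sided exact permutation test (p = 0.179, smallest possible 0.0357). Neither line passed by itself (exact permutation p = 0.4 for OE1, smallest possible 0.2, and p = 0.3 for OE4, smallest possible 0.1). Long domains, of over 10 kb after joining peaks closer than 3000 bp, numbered 5522 ± 842 in EV and 4659 ± 617 in OE (SD, n = 3 and 5, exact permutation p = 0.214). The median peak was 1000 ± 52.4 bp wide in EV and 917 ± 50.9 bp in OE (SD, exact permutation p = 0.107). TSS windows, 5 kb either side of protein-coding transcription start sites, held 7.67% of the covered bases in EV and 7.59% in OE (exact permutation p = 0.536).

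**Figure D1:**
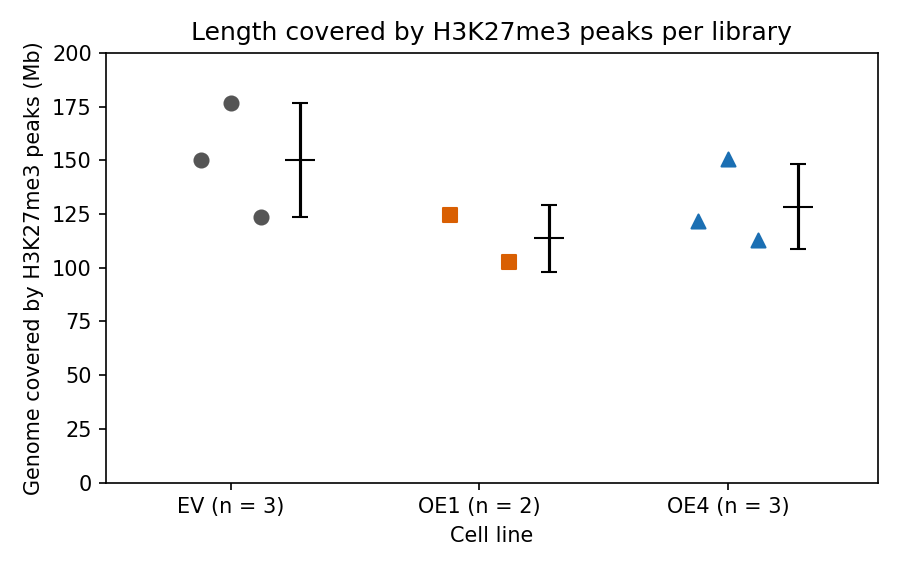
Length of genome covered by H3K27me3 peaks (Mb, vertical axis) in each library of EV, OE1 and OE4 (horizontal axis), with the mean and SD of each line beside its points. EV libraries lie between 123.7 and 176.6 Mb and OE libraries between 102.6 and 150.7 Mb, so the ranges overlap.

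On average, libraries of the same line covered more of the same bases than libraries of different lines, although single pairs overlapped: EV replicate 2 and OE4 replicate 2 reached 0.454 on the index below, above the OE1 pair. The Jaccard index, shared over joint covered bases, averaged 0.50 within EV, 0.447 within OE1 and 0.454 within OE4. Between lines it averaged 0.398 for EV and OE1, 0.409 for EV and OE4, and 0.395 for OE1 and OE4. The mean within lines exceeded the mean between lines by 0.0709, the largest of 280 assignments of the libraries to lines (permutation p = 0.00357, the smallest possible).

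The main comparison, of the pooled libraries of both NOP16 lines against EV, asked which genes differed in H3K27me3 around their start sites. Its p-values treat libraries as replicates, although they came from 1 EV line and 2 OE lines. They therefore cannot show how far independent lines differ. Loss was the common direction. FBXL7, which encodes an F-box subunit of a ubiquitin ligase (chromosome 5, 15500180 to 15939795), went from 63.8 ± 1.17% of its TSS window covered in EV (SD, n = 3) to 4.71 ± 3.22% in OE (SD, n = 5; limma adjusted p = 1.9e-04). DLK1, an imprinted gene for a Notch-like membrane protein (chromosome 14, 100725705 to 100738224), went from 72.8 ± 1.92% to 24.4 ± 7.48% (limma adjusted p = 0.00498). The serotonin receptor gene HTR1F lost cover from 71.4 ± 9.22% to 19.0 ± 15.3%, and the secreted-factor gene FAM3D from 52.0 ± 4.51% to 7.98 ± 9.59%. Gains were few. LDB2, a cofactor of LIM-domain transcription factors (chromosome 4, 16501541 to 16898678), went from 18.7 ± 6.56% to 62.3 ± 25.8% (limma adjusted p = 0.0447), and SHH, the Sonic hedgehog ligand (chromosome 7, 155799980 to 155812463), from a listed 0 in all EV libraries to 30.5 ± 10.2% (limma adjusted p = 0.0225).

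In all, 6 TSS windows gained and 146 lost cover among 3254 tested of 19962 (limma, Benjamini-Hochberg adjusted p below 0.05), and 766 had an unadjusted p below 0.05. The other windows with the largest losses, all with every OE library below every EV library, belonged to GLYATL2, GJB5, MAS1, CNNM1, TESPA1 and MAT1A. MAT1A, the liver methionine adenosyltransferase, held 96.0 ± 7.02% in EV and 52.5 ± 16.3% in OE. GJB5, a gap junction connexin, held 73.2 ± 8.66% and 28 ± 23.7%. The potassium channel gene KCNA5 gained from 40.6 ± 11% to 74.9 ± 3.27% (limma adjusted p = 0.0220). HAO2, a peroxisomal oxidase gene, and the receptor gene GPR31 were listed at 0 in EV and gained to 29.9 ± 11.9% and 15.9 ± 3.28%, while the olfactory receptor gene OR10D3 gained from 9.55 ± 9.78% to 38.0 ± 8.79%. The calls were kept in 13 of 19 other settings for HAO2, 4 of 18 for GPR31 and 8 of 21 for OR10D3, whose difference reversed to -0.455 points with peaks of -log10 q of at least 3. Over all tested windows the median difference was -6.0 percentage points. With every library trimmed to the same covered length, 12 windows gained and 45 lost, of which 40 were among the 152, and the median difference was -2.59 points. Trimming equalizes the genome total, which by itself lowers an excess of losses but does not fix the balance in TSS windows. With quantile normalization 26 gained and 46 lost, of which 51 were among the 152. FBXL7, DLK1, KCNA5 and LDB2 passed under both, LDB2 with a gain of 52.6 points at equal covered length, but over all other settings the calls were kept in 6 of 20 for LDB2, 7 of 20 for GJB5, 10 of 20 for TESPA1, 13 of 21 for KCNA5, 14 of 20 for SHH, 19 of 21 for DLK1 and 19 of 19 for FBXL7. Single libraries moved the count: it was 34 without EV replicate 1, 12 without EV replicate 2, 228 without EV replicate 3, 88 and 82 without OE1 replicate 1 or 2, 52 without OE4 replicate 1, 233 without OE4 replicate 2 and 30 without OE4 replicate 3. Of the 24 genes named for this comparison that passed, 4 still passed without EV replicate 2 and 8 without EV replicate 1, FBXL7 and DLK1 among them in both cases. It was 12 without OE4 replicate 1 and 11 without OE4 replicate 3. LDB2, KCNA5 and SHH did not pass when EV replicate 1 or EV replicate 2 was left out.

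**Figure D2:**
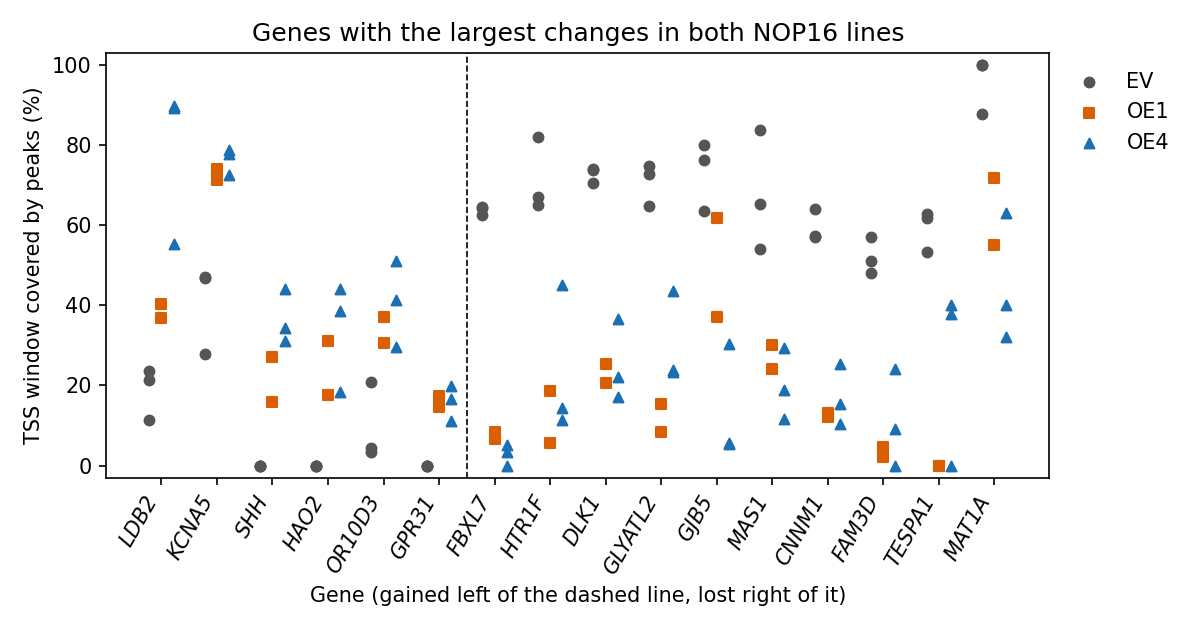
Percentage of the TSS window covered by peaks (vertical axis) in each library of EV, OE1 and OE4 (points). Genes (horizontal axis) are those with the largest gains and losses in the pooled comparison of both NOP16 lines with EV. FBXL7 shows the largest loss, from a mean of 63.8% in EV to 4.71% in OE, and LDB2 the largest gain, from 18.7% to 62.3%; at equal covered length both keep their direction.

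Several developmental and neuronal genes had highly covered start sites in EV. Among developmental transcription factors, 44 of 92 TSS windows were covered enough to be tested, with a list mean of 20.1% in EV and 15.6% in OE. NKX2-1, a lung and thyroid regulator, fell from 94.0 ± 10.3% to 66.2 ± 11.1% (limma adjusted p = 0.0421), and PDX1, a pancreas regulator named after its values were seen, fell from 24.2 ± 3.74% to 4.77 ± 5.69%; 42 did not pass. The NKX2-1 call was kept in 6 of 21 other settings. LHX2, a forebrain regulator, held 87.5 ± 0.592% in EV and 87.1 ± 1.83% in OE. Adjusted over the list alone, 0 gained and 2 lost. Among neuronal channel and receptor genes, 32 of 63 were tested (24% in EV, 18.5% in OE), and 3 lost cover. These were KCNJ6, an inward rectifier potassium channel (70.4 ± 7.90% to 29.4 ± 5.70%), GRIN2B, an NMDA receptor subunit (47.1 ± 23.7% to 8.12 ± 5.11%), and KCNA4, a voltage-gated potassium channel (56.1 ± 13.8% to 21.1 ± 12.1%). The calls were kept in 18 of 21 other settings for KCNJ6, 13 of 21 for GRIN2B and 10 of 21 for KCNA4, whose difference reversed to 1.16 points with peaks of -log10 q of at least 3. Adjusted over the list alone, 0 gained and 4 lost. Among imprinted genes, 7 of 27 were tested (16.5% and 11.5%), and DLK1 and the growth factor gene IGF2 (54.4 ± 9.68% to 17.5 ± 10.2%, limma adjusted p = 0.0219) lost cover, as they did adjusted over the list alone. GNAS and RTL1 did not pass, at 70.8 ± 1.74% and 88.8 ± 12.2% in EV and 65.9 ± 8.92% and 75.6 ± 12.9% in OE. The HOX genes, which pattern the body axis, had 9 of 39 tested (9.16% and 8.0%), and none passed over both lines (limma, 0 also adjusted over the list alone). HOXB13 held 66.8 ± 19.1% in EV and 44.8 ± 7.21% in OE, and HOXC6 1.02 ± 1.76% and 12.4 ± 13.1%.

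Several epithelial genes were covered in EV. Among luminal epithelial genes 9 of 34 were tested (12.2% in EV, 9.41% in OE) and none passed over all windows, while 1 lost adjusted over the list alone. FOXA1, a luminal pioneer factor, held 82.8 ± 5.59% in EV and 82.9 ± 5.91% in OE. Among basal epithelial genes 5 of 23 were tested (12.2% and 9.29%) and none passed, with TRIM29 at 96.9 ± 5.29% and 81.1 ± 11.4% and the keratin gene KRT5 at 68.2 ± 8.74% and 48.7 ± 10.3%. Among mesenchymal genes 3 of 37 were tested (4.23% and 3.54%) and none passed. THY1 held 80.6 ± 8.41% and 80.4 ± 8.86%. Among cell cycle inhibitors and tumour suppressors 6 of 35 were tested (6.88% and 6.85%), and the Wnt antagonist gene WIF1 fell from 16.9 ± 3.22% to 2.21 ± 3.65% (limma adjusted p = 0.0451), a call kept in 4 of 18 other settings, and it was the 1 loss adjusted over the list alone. The adhesion gene CADM1 held 73.4 ± 1.86% and 73.9 ± 3.86%. Interferon and antigen presentation genes had 9 of 42 tested (6.23% and 4.22%), 0 passing over all windows and 1 lost adjusted over the list alone. HLA-F held 18.6 ± 1.48% and 4.80 ± 3.22% (limma adjusted p = 0.0704). Cytokine and chemokine genes had 7 of 34 tested (5.33% and 5.42%) and none passed, with CXCL14 at 96.7 ± 5.77% and 92.3 ± 7.02%.

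Housekeeping groups were nearly free of peaks. Ribosomal protein genes had 1 of 78 windows tested, RPL38 (23.1 ± 3.98% in EV, 24.7 ± 7.75% in OE), and list means of 0.333% and 0.334%. Ribosome biogenesis and nucleolar genes had 3 of 40 tested (0.601% and 0.825%), NOP16 itself among them, and none passed. Genes of PRC2 and the H3K27 demethylases had 0 of 15 tested (0.345% and 0.222%), and proliferation genes 0 of 38 (0.104% and 0.0186%). Replication-dependent histone genes had 2 of 69 tested (0.181% and 0.296%), none passing. Zinc finger genes of the ZNF series had 30 of 508 tested (1.56% and 1.13%), and ZNF648 fell from 57.0 ± 4.29% to 22.4 ± 6.71%, while 5 lost adjusted over the list alone. Clustered protocadherins, neuronal adhesion genes, had 9 of 53 tested (2.65% and 2.83%), and PCDHAC2 fell from 54.3 ± 10.9% to 17.5 ± 13.6%, also adjusted over the list alone, a call kept in 9 of 20 other settings. Haematopoietic markers had 14 of 32 tested (14.0% and 13.7%) and none passed. The T-cell receptor genes CD3D and CD3G held 42.6 ± 13.2% and 53.8 ± 8.81% in EV and 67.4 ± 10.9% and 74.9 ± 12.4% in OE. Hepatocyte and muscle markers had 14 of 30 tested (23.8% and 20.2%) and none passed, while 1 lost adjusted over the list alone. The cardiac myosin gene MYH7 held 95.8 ± 5.04% and 67.2 ± 16.4% (limma adjusted p = 0.0545). Olfactory receptors had 152 of 400 tested (13.0% and 12.0%). OR10D3 gained, and OR8S1, OR6S1, OR4E1, OR2V2 and OR1K1, named after their values were seen, lost cover; adjusted over the list alone, 1 gained and 4 lost. In single lines but not over both, HOXC6 gained (20.6 ± 9.26%, limma adjusted p = 0.0443) and NKX2-2 and DRD1 lost cover in OE4 (limma adjusted p = 0.0191 and 0.0443), and HLA-DPB1 lost cover in OE1 (limma adjusted p = 0.0384), all chosen after their values were seen. Olfactory receptors lost cover at 5 windows in OE1, and in OE4 gained at 3 and lost at 7.

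As a set against other tested windows, the olfactory receptors moved less downward than the rest, which camera called Up (median -1.99 points against -6.0 for all windows, adjusted p = 0.0045 over 14 lists). With an estimated correlation the adjusted p was 0.694, so that call was not kept. No other of the 14 lists with at least 5 tested members passed, from adjusted p = 0.151 for imprinted genes, protocadherins and haematopoietic markers to 0.820 for hepatocyte and muscle markers. Camera's direction is relative to other windows, and it was Up despite a negative median and mean for olfactory receptors, HOX genes (median -2.16 points), haematopoietic markers (-2.07) and hepatocyte and muscle markers (-5.87). It was Up for protocadherins (median 2.13, mean -0.653), tumour suppressors (median 0.464, mean -0.173) and cytokine genes (median -0.365, mean 0.772), whose median and mean differed in sign.

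In OE1 alone, losses outnumbered gains without scaling. SBSPON, an extracellular matrix gene, went from 78.5 ± 17.9% in EV (SD, n = 3) to 18.7 ± 3.69% in OE1 (SD, n = 2), TESPA1, a T-cell signalling gene, from 59.3 ± 5.15% to a listed 0, and the growth factor gene FGF10 from 70.8 ± 5.4% to 18.2 ± 1.94%. FBXL7 and HTR1F also lost cover, to 7.51 ± 1.22% and 12.1 ± 9.34%. Gains included SETBP1, a SET-binding protein gene (10.0 ± 5.77% to 46.8 ± 2.26%, limma adjusted p = 0.0227), and the myosin gene MYO3A (52.4 ± 9.75% to 89.0 ± 15.5%). The remaining largest losses belonged to GLYATL2, OR6V1, RGS8, OTOP3 and SOHLH1. With limma, 3 windows gained and 98 lost, and 762 had an unadjusted p below 0.05. At equal covered length the limma count was 0, with 486 windows at an unadjusted p below 0.05, and none of the 13 genes with the largest changes in OE1 passed. With quantile normalization, which evens out gains and losses by construction, 36 gained and 48 lost. The count was 2 without EV replicate 1 or EV replicate 2, 244 without EV replicate 3, 34 without OE4 replicate 1 and 61 without OE4 replicate 3. It was 0 without OE1 replicate 1 or OE1 replicate 2 (550 and 380 windows at an unadjusted p below 0.05), where the lone OE1 library was assumed to vary like the other groups.

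In OE4 alone, losses again outnumbered gains. LDB2 rose from 18.7 ± 6.56% in EV to 78.1 ± 19.8% (SD, n = 3, limma adjusted p = 0.00929), and PIFO, a gene of primary cilium disassembly, from 4.60 ± 2.08% to 59.8 ± 2.80% (limma adjusted p = 8.04e-04). MS4A4E rose from 23.9 ± 7.28% to 78.4 ± 3.82%. The cornified envelope genes SPRR2G and LCE1E, of the epidermal barrier, rose from 55.5 ± 3.34% and 26.2 ± 7.03% to 93.5 ± 7.39% and 60 ± 0.279%. Their calls were kept in 13 of 20 and 12 of 20 other settings. The LCE1E difference reversed to -1.58 points with peaks closer than 3 kb merged. SHH, KCNA5 and HAO2 gained as well, and so did GNG5B and AMMECR1, which share most of 1 window and whose calls were each kept in 3 of 18 other settings. FBXL7 fell to 2.84 ± 2.62% (limma adjusted p = 6.97e-04), GJB5 to 13.7 ± 14.4%, and PCSK6, a proprotein convertase gene, from 66.3 ± 23.7% to 12.7 ± 15.0%. TENM1, a teneurin gene, fell from 68.5 ± 11.1% to 19.3 ± 19.5%, EPPK1, which encodes epiplakin, from 66.1 ± 6.99% to 17.6 ± 12.1%, and OR5V1 from 62.3 ± 7.00% to 16.5 ± 10.0%; DLK1, HTR1F, MAS1 and MAT1A also lost cover. Of the 21 genes named for OE4 that passed, 6, 5 and 18 still passed without EV replicate 1, 2 and 3. Without OE4 replicate 1, 2 and 3 it was 4, 15 and 6. The PCSK6 call was kept in 9 of 19 other settings. With limma, 25 windows gained and 118 lost, and 752 had an unadjusted p below 0.05. At equal covered length 48 gained and 74 lost. The count was 22 without EV replicate 1, 14 without EV replicate 2, 241 without EV replicate 3, 71 and 69 without OE1 replicate 1 or 2, 14 without OE4 replicate 1 and 9 without OE4 replicate 3, and PIFO and FBXL7 passed in each of these.

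The NOP16 lines were compared with each other to ask whether their changes were shared. FBXL7, DLK1 and HTR1F each lost cover in both lines (limma adjusted p = 0.0069, 0.0227 and 0.0227 in OE1, and 6.97e-04, 0.0103 and 0.0191 in OE4). Of the TSS windows called lost, 42 were shared by OE1 and OE4, and none of the gains was shared. At equal covered length OE1 had 0 called windows, so no shared call remained, FBXL7, DLK1 and HTR1F included. Both contrasts use the same EV libraries, and the overlap of calls was not tested against that. PIFO was the 1 window past the limma threshold between the lines, at 0 in both OE1 libraries and 59.8 ± 2.80% in OE4 (difference 59.8 points, adjusted p = 0.00235), and 429 windows had an unadjusted p below 0.05. The count was 0 without either OE1 library (290 and 252 windows at an unadjusted p below 0.05) and 2 without OE4 replicate 1. Across TSS windows, which are not independent replicates, the changes in OE1 and OE4 correlated with r = 0.584 (covariance 96.4). Simulated unchanged groups sharing the EV libraries gave r = 0.447 and a covariance of 29.8, so part of the correlation comes from the shared controls. With the EV libraries divided between the lines, 1 for a line and the others for the second, the 6 divisions gave r = 0.306 to 0.385 and a covariance of 60.2 to 75.8. All of these libraries still came from 1 EV line.

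NOP16 itself was free of peaks in EV and had peaks inside the gene in every OE library. Its TSS window (chromosome 5, gene at 176383946 to 176388927, minus strand) was covered by a listed 0 in EV (n = 3), 4.28 ± 0.0141% in OE1 (n = 2) and 14.7 ± 0.204% in OE4 (n = 3). The gain passed in OE4 (limma adjusted p = 0.0449) but not in OE1 (limma adjusted p = 0.573) or over both lines (limma adjusted p = 0.129), and the OE4 call was kept in 4 of 17 other settings and was lost on leaving out any 1 of the 8 libraries. In all 5 OE libraries a peak lay in the intron between exons 4 and 5, from 176384736 to 176385162 in OE1 replicate 1 and from 176384682 to 176385176 in OE4 replicate 3, and overlapped no exon base of the canonical transcript. Its -log10 q was the highest of the library, at 34.2 and 29.4 in OE1 and 49.3, 59.7 and 64.7 in OE4, where the next highest peak had between 12.3 and 25.2. Its fold enrichment, 1.71 and 1.76 in OE1 and 1.89, 2.02 and 2.05 in OE4, was among the lowest, with at most 2 peaks of the library lower, against library medians of 3.35 to 3.60. Both values depend on the control library and thresholds of the peak caller, which are not given in the sources used here. A second peak in the intron after exon 2 appeared in the OE4 libraries, with folds of 1.3, 1.37 and 1.26. HIGD2A, which starts beside NOP16, has the same covered bases in its window.

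**Figure D3:**
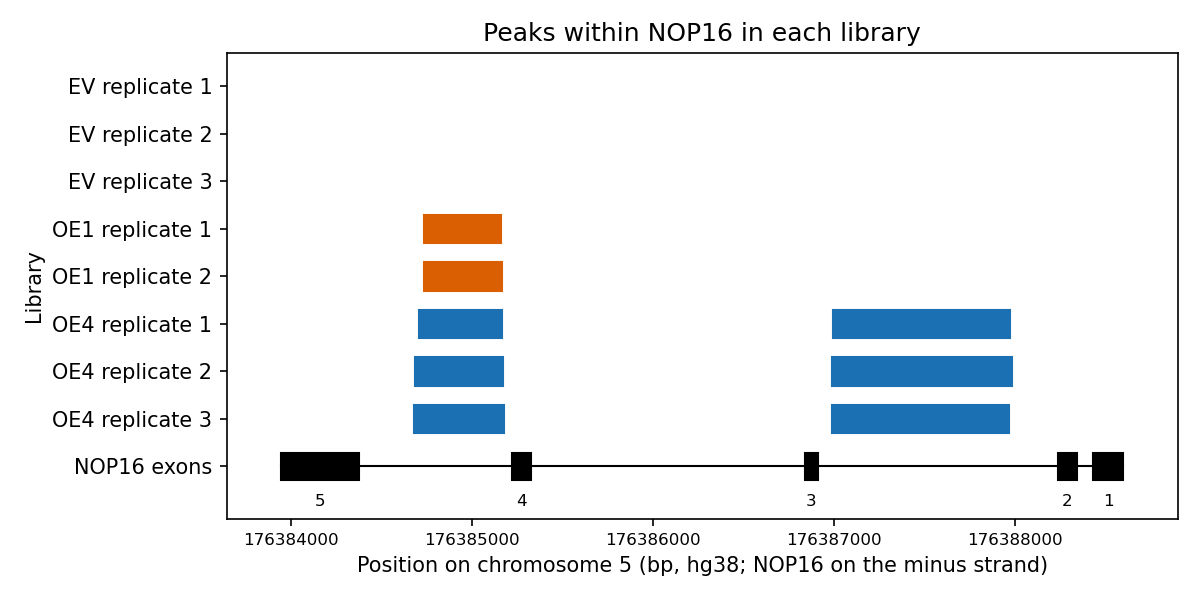
Peaks in each library (coloured bars, vertical axis) along NOP16 on chromosome 5 (position in bp, horizontal axis), with the 5 numbered exons of the canonical transcript in black. The EV libraries show 0 peaks, OE1 libraries 1 each, and OE4 libraries 2 each, all within introns.

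Genome-wide bins of 50 kb showed changes both within genes and in regions without protein-coding genes. The strongest losses lay near the end of chromosome 10, where a bin from 1950001 to 2000000 without a protein-coding gene went from 67.7 ± 2.82% in EV (SD, n = 3) to 2.34 ± 0.736% in OE (SD, n = 5, limma adjusted p = 1.1e-09) and a region from 2350001 to 2450000 from 74.8 ± 7.19% to 19.2 ± 3.69%. Bins within RGS6, a regulator of G protein signalling (chromosome 14, 72150001 to 72200000), and CTNND2, a neuronal catenin (chromosome 5, 11100001 to 11150000), fell from 78.2 ± 3.99% to 28.4 ± 12.1% and from 87.8 ± 7.29% to 38.9 ± 9.49%. Several of the largest gains lay in TENM2, a teneurin gene on chromosome 5, where 167250001 to 167350000 rose from 10.5 ± 1.62% to 43.3 ± 2.72% and 167500001 to 167550000 from 33.7 ± 11.8% to 68.3 ± 8.21%. Another TENM2 bin, at 167950001 to 168000000, rose from 14.7 ± 2.6% to 47.6 ± 4.50%, and a bin with the potassium channel gene KCNA1 (chromosome 12, 4900001 to 4950000) from 37.2 ± 6.67% to 72.4 ± 4.95%. In all, 150 bins gained and 1652 lost among 10059 tested (limma). Here too libraries, and not lines, were the replicates behind each p-value. At equal covered length 680 gained and 762 lost, and with quantile normalization 808 gained and 960 lost; both settings equalize cover between libraries, which by itself evens out gains and losses. The count of 1802 was 812 without EV replicate 1 and 525 without EV replicate 2.

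By line, 142 bins gained and 1799 lost in OE1, and 429 gained and 1670 lost in OE4. At equal covered length the numbers were 742 and 704 in OE1 and 1020 and 985 in OE4. The lines, which share the EV libraries, had 977 lost and 53 gained bins in common, and 4 bins went opposite ways. The OE4 and OE1 libraries differed from each other in 488 bins, 378 higher and 110 lower in OE4, and in 258 higher and 301 lower at equal covered length. Across bins the changes in OE1 and OE4 correlated with r = 0.672 (covariance 57.4), against r = 0.445 and a covariance of 11 in simulated unchanged groups with shared EV libraries. With the EV libraries divided, r was 0.485 to 0.577 and the covariance 44.2 to 54.6. The OE1 count was 1146 without EV replicate 1, 1014 without EV replicate 2, 3128 without EV replicate 3, 1016 without OE1 replicate 1 and 484 without OE1 replicate 2. The OE4 count was 1292 without EV replicate 1, 1254 without OE4 replicate 1 and 1325 without OE4 replicate 3, and the count between lines 66 without OE1 replicate 1, 119 without OE1 replicate 2 and 218 without OE4 replicate 2.

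**Figure D4:**
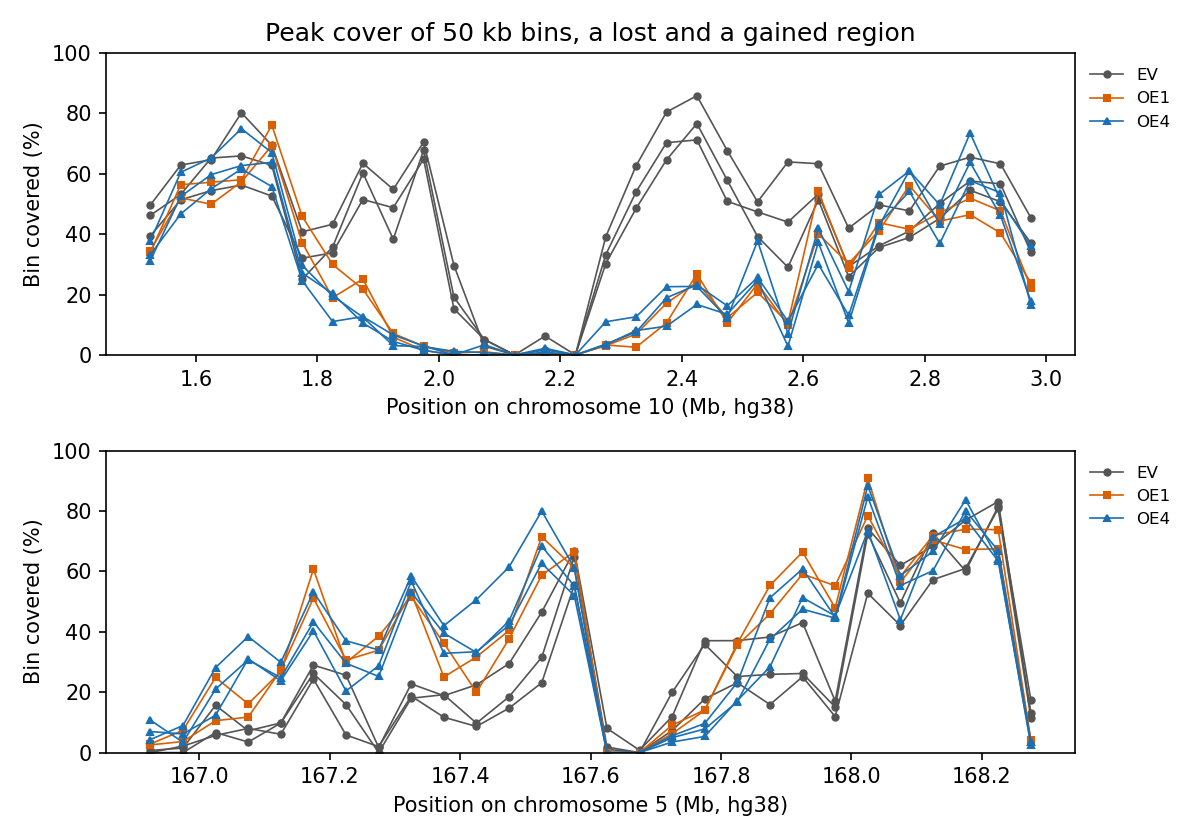
Percentage of each 50 kb bin covered by peaks (vertical axis) along a part of chromosome 10 that lost cover and the TENM2 part of chromosome 5 that gained it (position in Mb, horizontal axis), 1 line per library coloured by cell line. In the bin at 1950001 to 2000000 on chromosome 10 the EV mean is 67.7% and the OE mean 2.34%.

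Covered bases were also compared by chromosome. Chromosome 1 held 10.3 ± 0.204% in EV and 11.1 ± 0.202% in OE, chromosome 12 held 4.47 ± 0.0650% and 4.93 ± 0.124%, chromosome 18 held 3.33 ± 0.0800% and 2.79 ± 0.143%, and chromosome 21 held 1.45 ± 0.0310% and 1.21 ± 0.0241%. EV and OE libraries did not overlap for 7 of 23 chromosomes (1, 9, 12, 13, 18, 19 and 21), each at the smallest possible exact permutation p of 0.0357. Benjamini-Hochberg adjustment over 23 chromosomes gave these an adjusted p of 0.117, and with so few libraries 7 chromosomes could not have passed, so the adjusted values show neither a difference nor similarity.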

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

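The tests of drift, of an EV line change and of other splits were chosen only after the results were seen, as was the normalization within GC deciles, although the bounds for GC content and copy number were set before their results.

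PIFO stood out because the NOP16 lines differed: OE4 exceeded OE1 by 59.8 percentage points of its TSS window, the 1 TSS window past the limma threshold between the lines (adjusted p = 0.00235, 0 in both OE1 libraries and 59.8 ± 2.80% in OE4, n = 3). Among 50 kb bins, 488 differed between OE4 and OE1. GATA4, KRT6B and GAS1 each had 1 OE library far from the other 4. The gap to the nearest library was 0.860 of the range of the 5 OE libraries for GATA4, 0.763 for KRT6B and 0.718 for GAS1. Such gaps arise by chance in about 1 in 20 groups, and the 3 among 85 groups tested were fewer than the 4.25 that chance gives.

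With both NOP16 lines pooled against EV, 1802 bins and 152 TSS windows changed. Any other of the 56 splits of the libraries gave at most 141 and 13 (1 split, the real one, gave as many). Splits that mix lines count differences between lines as spread, which by itself lowers their counts. The splits therefore show only that libraries grouped by line. The 141 and 13 came from setting OE4 apart, the only other split that keeps each line whole. The 3 lines are too few to exclude chance differences between lines. For OE4 against EV the 10 splits are too few for a share under 0.05 (143 windows and 2099 bins, highest other 0 and 0, 1 split as large in each case). Normalization within GC deciles left 87.1% as many called bins as plain quantile normalization (1540 against 1768, with 1372 called by both in the same direction). This argues against GC content as the source of most called bins. At equal covered length, bins 0.5 to 5 Mb from a called bin moved by 0.0986 of its change (95% interval 0.0545 to 0.150). Without trimming they moved by 0.142 (95% interval 0.0778 to 0.205). This argues against long copy number segments that move all their bins alike as the source of most called bins. Called bins were picked for large changes, which by itself lowers this share, and how peak cover follows copy number was not tested. As an average the share cannot exclude shorter segments or changes of single chromosomes. EV and OE cover shares did not overlap on chromosomes such as 12, higher in OE, and 18, lower in OE. Copy number was not tested there. The component specific to EV was 2.74 times the larger OE one at equal covered length (95% interval 2.13 to 3.36). This component is the covariance of the OE1 and OE4 changes beyond that of shared controls, so it restates the shared changes. The interval resampled chromosomes and not lines, so the ratio cannot decide on equal drift of 3 independent lines. Drift, equal or unequal, stays open. An effect of NOP16 overexpression and a change of the single EV line itself, with a component of 70.5 squared percentage points, cannot be told apart, because there was 1 control line. Any of these may account for the shared changes, including those at FBXL7 and DLK1.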

How the results depend on the processing

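Normalization within GC deciles, quantile normalization for the gene lists and division of the EV libraries between the lines were tests chosen only after the results were seen. The covered length was lower in OE than in EV in every setting run, by -19.8 to -32.1 Mb, and without single libraries by -14.4 to -40.8 Mb, and never passed its exact permutation test; equal covered length fixes it and gave no value. Overlap within lines exceeded overlap between lines in every setting run, by 0.0582 to 0.0918. The chromosome shares gave 0 calls in all settings, which the smallest p of their exact permutation tests nearly fixes and which says nothing about stability. The depth, which is unknown, limits how much of any difference in covered length can be read as a difference in the mark. Unless a cause is named below, the cause was not tested.

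Counts below are of TSS windows, then of 50 kb bins, past the limma threshold. Mainly counts that moved far from the main result are listed, and those not listed stayed closer to it. Those for both lines are from the pooled comparison with EV and do not count calls shared by OE1 and OE4. With peaks of -log10 q of at least 3, 13 windows changed in both lines, 0 in OE1, 2 in OE4 and 0 between OE lines, and 83, 0, 6 and 0 bins; fewer windows (1592) and bins (3889) could be tested, and at an unadjusted p below 0.05 the counts of 0 were 198 and 111 windows and 615 and 152 bins. The line correlation over windows was then 0.535 and no gene list passed (0, camera). At equal covered length the windows numbered 57 in both lines, 0 in OE1 (486 unadjusted) and 0 between lines (347). With peaks closer than 3 kb merged there were 66 windows in both lines, 95 in OE4 and 46 between lines, and 1010, 889, 1302 and 120 bins in both lines, OE1, OE4 and between lines, with 2 gene lists and line correlations of 0.537 and 0.616. With windows of 2 kb there were 74, 2, 38 and 0 (341 unadjusted), in that order. Without a filter on the mean, which adds features to test, there were 77 windows in both lines, 24 in OE1 and 57 in OE4, and 1131, 844, 1321 and 70 bins. With a mean of at least 0.2 there were 82 windows in both lines and 83 in OE4, and 993, 1083, 973 and 195 bins. The arcsine square root gave 86 windows in both lines, 76 in OE4 and 8 between lines, and 742 bins between lines. Quantile normalization gave 72 windows in both lines and 48 between lines, and 3249 bins in OE4 and 1831 between lines. The peaks above the median fold gave 63 windows in OE1 and 0 between lines (358 unadjusted), and 1193, 981, 1188 and 42 bins, with 0 gene lists. Gene bodies gave 207 windows in both lines, 130 in OE1, 185 in OE4 and 9 between lines, and 3 gene lists. The 3-group design gave 215 windows and 2444 bins in both lines. Bins of 10 kb gave 3317 changed in both lines. Limma without trend and robust gave 1231 bins in OE1, 1352 in OE4 and 67 between lines. With an estimated correlation camera called 0 lists (olfactory receptors adjusted p 0.694, over all settings 4.3e-05 to 0.966). With at least 50% of the window covered, 1 window, KCNA5, was in all OE and no EV libraries, against at most 18 in any other split. In all EV and no OE libraries there were 44, against at most 26 in any other split, and the longer cover in EV by itself favours these.

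With the replicate number as a block, 284 windows changed in OE1 and 7 between lines, and 3430 and 1147 bins, against 140 windows in both lines and 176 in OE4. Deviations from the line means correlated at -0.175 to 0.234 over the 7 same-numbered pairs of libraries in bins, 2 of them over 0.1, and at -0.112 to 0.0869 in windows, so the numbers were not taken to pair the libraries.

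Leaving out 1 library gave 12 to 233 windows in both lines, 0 to 244 in OE1, 9 to 241 in OE4 and 0 to 2 between lines, and 525 to 2374, 484 to 3128, 1254 to 2763 and 66 to 704 bins; the line correlations were 0.504 to 0.643 over windows and 0.623 to 0.717 over bins. The EV libraries divided between the lines gave mean correlations of 0.352 over windows and 0.543 over bins; no control is then shared, but each line also had fewer EV libraries, and these causes were not separated.

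Of the 58 gene results past the threshold, other settings gave 675 values, of which 440 stayed past it in the same direction, 232 kept the direction only and 3 reversed. Without single libraries 252 of 464 stayed past it, 212 kept the direction only and 0 reversed. FBXL7 in both lines and PIFO in OE4 stayed past it in all 19 settings that tested them. The 57 results not past it gave 674 values, 637 the same, 12 past it and 25 reversed, and without single libraries 434 of 454 the same, 11 past it and 9 reversed. The reversals, in percentage points for both lines unless stated, were these. With -log10 q of at least 3: OR10D3 -0.455, RPL38 -1.91, OVOL1 9.27, KRT6A 7.85, ZNF334 9.20, KCNA4 1.16, MPO 1.53 and TAT 5.52. At equal covered length: MMP2 7.45, CCL5 0.971, PCDHA1 0.153 and MYH2 3.63. With peaks merged: LCE1E -1.58 in OE4, CCL5 36.6, H2BC26 -0.0300 and TAT 12.6. With windows of 2 kb: MMP2 3.77, THY1 4.16 and CCL5 7.89. With quantile normalization: EBNA1BP2 1.52, MMP2 0.366, THY1 8.96, CXCL14 1.37 and CCL5 4.28. With peaks above the median fold: ESRP1 3.56. With gene bodies: PCDHAC1 -2.92, ZNF334 4.69 and H2AC25 -16.8. Without single libraries: EBNA1BP2 -11.8 to 4.03, RPL38 -1.38 to 3.55, THY1 -3.64 to 4.49 and CCL5 -7.69 to 0.650.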

Other observations

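The test of the share of covered bases in TSS windows, the tests of the NOP16 peaks and the use of equal covered length, a setting chosen beforehand, to weigh the excess of losses were chosen only after the results were seen.

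Lost bins formed 1061 runs of adjacent bins, of which 754 were single bins and 17 spanned at least 7 bins. The longest, on chromosome 7 from 155950001 to 156550000, spanned 12 bins (600 kb) beyond the SHH gene and went from a mean of 44.1% covered in EV to 20.7% in OE, although the SHH window itself gained. Runs on chromosome 13 covered FLT1, a VEGF receptor gene (28300001 to 28650000, 28.9% to 1.90%), and FGF9, a growth factor gene (21700001 to 22100000, 49.4% to 25.6%). RGS6 on chromosome 14 lay in a run of 8 bins (71900001 to 72300000, 61.7% to 27.8%). Runs at BCOR, a Polycomb-associated corepressor gene on chromosome X, and at PTPRN2 on chromosome 7 went from 29.9% to 13.1% and from 33.6% to 15.2%. The longest gained run was the 6 bins of TENM2 from 167250001 to 167550000 on chromosome 5.

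Some TSS windows had a peak in every library of 1 kind and none of the other. A total of 39 windows had peaks in all EV and no OE libraries, among them those of SNAI1, a mesenchymal transcription factor (7.26 ± 5.04% in EV), and the neuronal glutamate receptor gene GRIA4, against at most 22 in any other split of the libraries. HAO2, OR10G8, FAM47E-STBD1, NOP16, HIGD2A, GPR31, SHH and HEPH, 8 windows, had peaks in all OE and no EV libraries, fewer than the 21 of the highest other split. The number in all 8 libraries was 2321. Peaks covered 150 Mb on average in EV and 122 Mb in OE, which by itself favours windows with peaks in EV only. No such count was made at equal covered length, and most other splits mix lines.

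With both NOP16 lines pooled, losses outnumbered gains by 1652 to 150 among 50 kb bins, and made up 91.7% of the changed bins. When every library was trimmed to the same covered length, 52.8% of the changed bins were losses, but equal totals even out gains and losses by construction, so this cannot show whether the smaller covered length of the OE libraries may account for the excess. For TSS windows the share of covered bases at equal covered length differed by -0.633 points (8.60 ± 0.270% in EV, 7.97 ± 0.340% in OE, exact permutation p = 0.0714). Trimming itself went with a higher share. EV replicate 2, which covered most, went from 7.50% to 8.87%, and OE1 replicate 2, which was not trimmed, stayed at 7.53%. EV libraries were trimmed more on average, so this difference cannot show whether start sites lost more than other bases. Untrimmed, the shares were 7.67% in EV and 7.59% in OE (exact permutation p = 0.536). A lower amount of the mark in NOP16 lines and a lower depth or efficiency of their libraries would both shorten the covered length, and depth is unknown.

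The NOP16 peak in every OE library joined the highest -log10 q with nearly the lowest fold enrichment. The fold lay at or below the 0.00263 percentile of the library's peaks. The lowest among the 100 peaks next in -log10 q lay at percentiles of 0.991 to 93.1 over the OE libraries. These are the values by which the peak stood out. They therefore cannot decide whether an ordinary gain of H3K27me3 at the endogenous gene was the whole source. Reads from extra copies of NOP16 sequence in the OE lines, such as the overexpression construct, may be the source, which stays open because it was formed on the same values, with an implied background of 68.2 to 83.8 times the library median. Fold, q and implied background at NOP16 also depend on the caller's control library and thresholds, which are not given in the sources used here. The peaks lay in introns with 0 exon bases, and a construct of exons alone would not contain the bases under them. Whether the construct held introns, and how its reads would be placed, was not tested.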
